A study of Danio rerio with 9 samples.

How the data were processed

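RNA of 9 pools of 60 zebrafish embryos was hybridised to 1-colour (Cy3) Agilent arrays, 3 each for embryos injected with GFP, Hif-1α or Hif-3α mRNA and collected at 12 h after fertilization. Per the file headers the arrays carry grid design 026437, a zebrafish design with 45220 spots, although the labelling protocol names a mouse array. The deposited file of each array gives the processed signal as an intensity, and the median signals of the spot and of its local background as intensities, from Feature Extraction 10.7.3.1. Per the file headers the processed signal is background-subtracted, with spatial and multiplicative detrending, and is not normalized between arrays. The deposited spot flags are other values, 0 or 1 for well above background, saturated or outlier. The authors normalized the data with GeneSpring 11.0, and the deposited matrix of processed values is in log2 units, with nearly identical quantiles on all 9 arrays.

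Each probe was joined through its RefSeq accession, without its version, to a symbol in the RefSeq gene table of assembly GRCz12tu. The table was used for names alone, since the array was built on another assembly, and no coordinates are given. Of 43603 probes 25069 received a symbol, 12858 symbols in all, and 18534 did not. The files have no column of gene names, which the plan had assumed, so the accession took its place. Spots of the same probe were averaged, control spots and 459 probe values with an outlier flag were left out, and no spot was saturated. Hif-3α replicate 1 held 437 spots with an outlier flag, against 3 to 24 on each other array. That array also had the lowest share of probes well above background, 68.6%. A probe was kept if it lay well above background on all 3 arrays of at least 1 group, which left 31117 probes. Where a gene had several probes, the brightest over all arrays stood for it. This gave 19541 genes or transcripts, 10637 with a symbol (723 of them clone or placeholder names) and 8904 without. Of 7451 genes with several probes, 317 that were not called for Hif-1α against control had another probe that was, 3 for Hif-3α against control and 50 for Hif-3α against Hif-1α.

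The log2 of the processed signal minus the 75th percentile of its array was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and 1 spread over all 9 arrays, and empirical Bayes moderation. The 3 comparisons were Hif-1α against control, Hif-3α against control and Hif-3α against Hif-1α, tested two-sided with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The median standard error of a log2 difference was 0.19. A fold is given as "at least" where no array of 1 group was well above background, and is then computed against the lowest signal that was. Where only some arrays of a group were, their number is given. A gene is called changed, higher or lower in the text when it passed.

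The 19 gene lists were HIF target genes, glycolysis, HIF pathway components, somites and muscle, notochord and axial mesoderm, neural, blood and vessel, epidermis and hatching gland, yolk layer and endoderm, neural crest, p53 and DNA damage, unfolded protein and amino acid response, heat shock, interferon response, oocyte and germline transcripts, cell cycle, circadian clock, oxidative phosphorylation and ribosomal proteins. Some lists share genes, so their results are not independent of each other. HIF target genes share aldocb, hk1, hk2 and ldha, among others, with glycolysis. They share egln1b and egln3 with HIF pathway components, and bhlhe40 and bhlhe41 with the circadian clock. The lists, the comparisons, the tests and the alternatives were fixed before the data were examined, except where stated. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 19 lists of a comparison. For Hif-1α against control 13 lists passed, for Hif-3α against control 3, and for Hif-3α against Hif-1α 11. With the correlation estimated from the data 0 lists passed in each comparison, and with fry, which does not compare a list with other genes, 15, 1 and 8 passed. Missing values were replaced by the group's mean for the list tests alone.

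Genes were named by a rule fixed in advance. It took every probe of the HIF alpha genes, and the 10 genes that rose most and the 10 that fell most by fold in each comparison, among genes that passed with the same direction in every array and had a proper symbol. Where fewer than 5 passed, it took the 10 genes with the smallest p, said not to pass. It added up to 3 passing members of each list with the smallest p, up to 4 HIF targets as values where no target passed, and igfbp1a, ddit4, mlp3c, sqor, zp3v2, vegfaa, epoa and egln3, known from the study or as HIF targets. mlp3c and zp3v2 could not be matched to a probe, and the 2 probes of epoa did not pass the filter on dim probes. The report gives a part of this set. Of the 62 named genes that passed for Hif-1α against control, 29 kept their call whichever 1 array was left out. For Hif-3α against Hif-1α 9 of 31 did. Among the genes counted as keeping their call, pkma (both comparisons) and rrm1 (Hif-1α against control) lacked a value on 1 array. They could be tested in 7 of the 9 fits with 1 array left out. Some genes that lost their call for Hif-1α, such as orc5, gng13b and per1b, are not given below.

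Arrays with the same replicate number were checked for pairing. After group means were removed, same-numbered arrays of Hif-1α and control had a correlation across genes of 0.110 to 0.467 (highest between other numbers 0.0695), those of Hif-3α and control 0.119 to 0.582 (0.0495), and those of Hif-3α and Hif-1α 0.470 to 0.539 (-0.02). Values with the experiment number as a block are therefore given where they change a named call or move a count of genes by more than 1.5 times. The file headers also show that the arrays were scanned on 4 days from 7 slides. Scan day 1 held control replicate 1, day 2 Hif-3α replicate 1, day 4 Hif-1α replicates 1 and 3, and day 3 the other 5 arrays. The scan day is therefore partly confounded with the groups, and a fit with the scan day as a block leaves 3 residual degrees of freedom. Day 3 alone held more than 1 group, so this fit takes the differences between groups from that day, which held 1 Hif-1α array.

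The alternatives were quantile normalization, the median of each array in place of its 75th percentile, normexp background correction with an offset of 50 followed by the 75th percentile or by quantile normalization (on the median signal, since the files hold no mean signal), the deposited matrix, no filter on dim probes, a filter on all 9 arrays, a trend of the spread with intensity, array weights, only the compared groups in the fit, the mean of the probes of a gene or every probe on its own, the experiment number or the slide as a block, thresholds with a 2-fold minimum, and each array left out in turn. The scan day as a block, and the experiment number as a block without each number in turn, were added after the data had been seen. The correlation and overlap of the responses were set beside 100 simulated data sets of unchanged groups against shared controls, and 100 more, added after the data had been seen, in which same-numbered arrays had the mean correlation of their residuals (0.287 for Hif-1α and control, 0.353 for Hif-3α and control, 0.499 for Hif-3α and Hif-1α). The model was tested on simulated data with the noise of these arrays and 19541 genes. Of 100 genes changed by 1 log2 unit and 100 changed by 2, it recovered 50% and 92% for Hif-1α against control, 55% and 93% for Hif-3α against control and 45% and 88% for Hif-3α against Hif-1α, with 8, 10 and 6 false calls. Over 20 simulations of 19 lists there was 1 false list call, and a glycolysis list moved by 0.5 was recovered in 20 of 20. On the real arrays the estimated correlation between genes of a list ranged from -0.00274 (p53) to 0.367 (ribosomal proteins). It was 0.159 for HIF targets and 0.288 for glycolysis. False calls and recovery of lists whose genes vary together to this degree were not tested. The simulated rates therefore do not bear on the list calls reported for such lists.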

Results

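Gene expression was measured in whole zebrafish embryos of the Tuebingen strain at 12 h after fertilization. The embryos had been injected with mRNA for green fluorescent protein (GFP, the control), for Hif-1α or for Hif-3α, 2 alpha subunits of the hypoxia-inducible factor (HIF), the transcription factor that responds to low oxygen. Each group held 3 arrays, each from the RNA of a pool of 60 embryos, and the 9 arrays came from 3 independent microinjection experiments. Between 68.6% and 75.3% of the 43603 probes lay well above background on each array, and any 2 arrays had a correlation of 0.948 to 0.991 across probes. The 75th percentile of the signal was 766, 822 and 795 on the control arrays, 500, 611 and 562 on the Hif-1α arrays and 609, 785 and 690 on the Hif-3α arrays. The number of arrays, 3 a group, limits the precision of every value. Levels are log2 signals relative to each array's 75th percentile, errors of differences are standard errors (SE) with n = 3 arrays a group, and p-values are adjusted over the 19541 genes or transcripts tested unless another family is named.

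The RNA of the injected Hif-3α was visible on the arrays. Its gene appears as hif1al, for which the reference table lists Hif-3alpha as a synonym, and it has 4 probes. Probe A_15_P281686 was 8.49 ± 0.16 log2 units higher in the Hif-3α embryos than in the controls, a 360-fold difference (adjusted p = 6.06e-07 over all probes). Probe A_15_P731526 was 6.41 ± 0.17 higher (adjusted p = 5.13e-06) and probe A_15_P404495 was 5.85 ± 0.20 higher (adjusted p = 2.55e-05). The brightest probe of the gene, A_15_P621106, differed by -0.02 ± 0.14, so the value that stands for hif1al in the tables by gene holds none of this difference. In the Hif-1α embryos the 4 probes differed from the controls by 0.13, 0.06, 0.08 and -0.05, none past the threshold. Probes could not be matched to hif1aa, hif1ab or epas1a, so the injected Hif-1α RNA could not be looked for under its own name. The 2 probes of epas1b were 0.45 and 0.62 higher with Hif-1α (adjusted p = 0.148 and 0.182 over all probes). The probe of hif1al2, a related gene, was well above background on 1 array alone, Hif-3α replicate 1, at -2.75, against a control mean of -8.12.

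**Figure D1:**
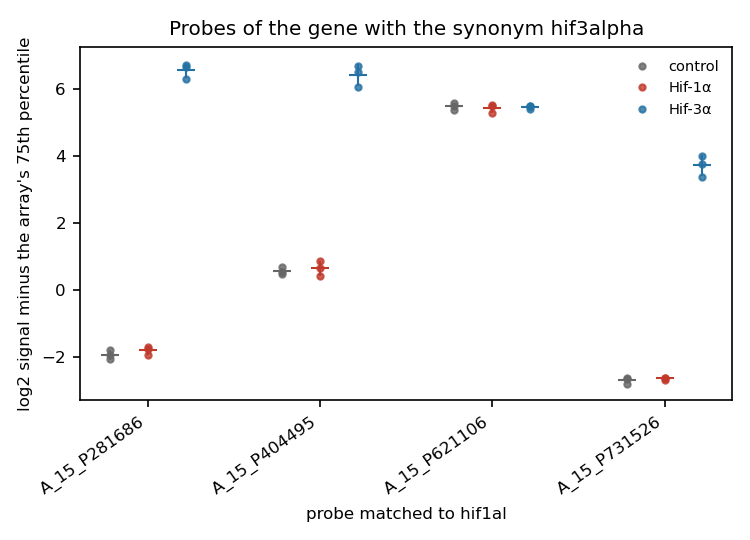
The vertical axis gives the log2 signal relative to each array's 75th percentile for the 4 hif1al probes, with control, Hif-1α and Hif-3α arrays side by side (points are arrays, ticks are means and bars are SD, n = 3). Probes A_15_P281686, A_15_P731526 and A_15_P404495 were 8.49, 6.41 and 5.85 log2 units higher with Hif-3α than in the controls, and probe A_15_P621106 differed by -0.02.

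Hif-1α embryos were compared with GFP controls to ask which genes respond to the injected Hif-1α. gapdhs, a glyceraldehyde-3-phosphate dehydrogenase, rose by 4.95 ± 0.29 log2 units or 30.8-fold (adjusted p = 0.000558), the enolase eno1b by 4.71 ± 0.50 (adjusted p = 0.00369) and the pyruvate kinase pkma by 3.50 ± 0.27 (adjusted p = 0.00219). pkma had no value on control replicate 1, so its control mean rests on the other control replicates. igfbp1a, a secreted binding protein of insulin-like growth factors, rose 15.9-fold (3.99 ± 0.56, adjusted p = 0.00839). vhl, which targets HIF alpha subunits for degradation, rose by 1.78 ± 0.22 (adjusted p = 0.0053). With limma, 1858 genes or transcripts changed, 1121 higher and 737 lower, of which 608 and 484 had a gene symbol. Of the changed genes, 776 differed at least 2-fold, 624 of them higher.

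Among the 10 genes that rose most by fold, ndufa4b (detected on 2 of 3 control arrays) and cox6b1, subunits of cytochrome c oxidase, rose 85.5-fold (6.42 ± 1.14) and 74.5-fold (6.22 ± 1.11), both with an adjusted p of 0.0172. The enolase eno1a rose by 5.61 ± 1.14 (adjusted p = 0.0248) and the aldolase aldocb by 5.11 ± 0.91 (adjusted p = 0.0172). These 4 genes varied widely among the controls: eno1a stood at 0.16, 5.23 and 2.55 in control replicates 1, 2 and 3, against 8.23, 8.35 and 8.19 in the Hif-1α arrays. Without control replicate 1 the differences of ndufa4b, cox6b1, eno1a and aldocb were 4.92, 4.71, 4.36 and 4.11, and without control replicate 2 they were 7.62, 7.40, 6.90 and 6.17. gpr132b, a G protein-coupled receptor (adjusted p = 0.00369), and vamp1b, a protein of vesicle fusion (adjusted p = 0.00266), also rose, and each was well above background on 1 of 3 control arrays, so no fold is given. The adrenergic receptor adra2db and the fast muscle myosin myhz2, which no control array detected well above background, were at least 7.80-fold and 6.72-fold higher. Among the genes that fell most were the tubulin tubb5 (-1.82 ± 0.27, adjusted p = 0.00975) and the lipoprotein lipase lpla (-1.73 ± 0.25, adjusted p = 0.00911). The adrenergic receptor adra1bb, well above background on 1 of 3 Hif-1α arrays, also fell (adjusted p = 0.00266), and no fold is given. Without control replicate 3, Hif-1α replicate 1 or Hif-1α replicate 3, ndufa4b, cox6b1 and aldocb no longer passed (adjusted p = 0.0553 to 0.0625). eno1a no longer passed without control replicate 1, control replicate 3 or any 1 of the Hif-1α replicates (adjusted p = 0.0544 to 0.0813).

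**Figure D2:**
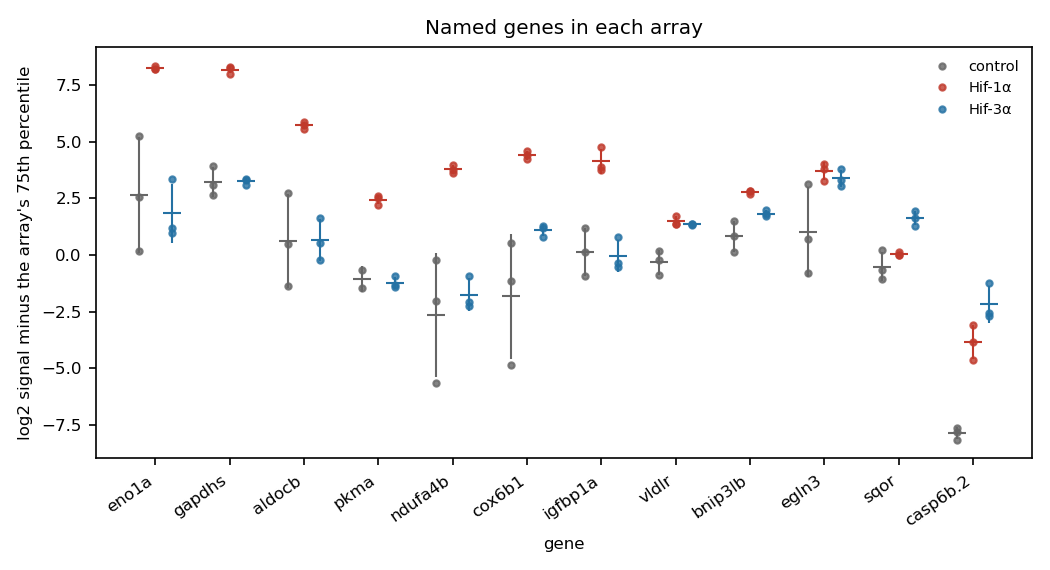
The vertical axis gives the log2 signal relative to each array's 75th percentile for named genes in control, Hif-1α and Hif-3α arrays (points are arrays, ticks are means and bars are SD, n = 3). gapdhs was 4.95 log2 units higher with Hif-1α than in the controls, and igfbp1a 3.99 log2 units higher.

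Of the gene lists fixed before the data were examined, the 39 measured HIF target genes had 15 members that rose and 1 that fell with Hif-1α, with a median log2 change of 0.75. Adjusted over the list alone, 23 rose and 2 fell. Among those that rose were igfbp1a, the lipoprotein receptor vldlr (1.79 ± 0.26, adjusted p = 0.00869) and bnip3lb, a receptor for the removal of mitochondria (1.95 ± 0.29, adjusted p = 0.0108). The list rose against other genes (camera, adjusted p = 2.58e-08), with an adjusted p of 0.183 when the correlation between genes was estimated. In glycolysis, 12 of 23 members rose and 1 fell, and 14 rose and 2 fell adjusted over the list alone. Its median change was 0.85 (camera, adjusted p = 2.28e-06), with an adjusted p of 0.208 with an estimated correlation. Of 12 HIF pathway components 2 rose, vhl among them, and 5 rose adjusted over the list alone, but the list did not pass (adjusted p = 0.0529) except without control replicate 2 or Hif-1α replicate 2 (adjusted p = 0.0335 and 0.0499) among the fits with 1 array left out. Blocked by experiment number, 4 of these components rose, and in oxidative phosphorylation 28 members fell and 5 rose. Oxidative phosphorylation moved both ways: 15 of 79 members fell and 5 rose, and 37 fell and 5 rose adjusted over the list alone. Its median change was -0.38 and its mean -0.10, or -0.03 without control replicate 3 (camera, adjusted p = 7.75e-08), with an adjusted p of 0.208 with an estimated correlation. The ATP synthase subunit atp5mc1 fell by 1.00 ± 0.16 (adjusted p = 0.0132, and 0.0510 without Hif-1α replicate 1), while cox5b2, a subunit of cytochrome c oxidase, rose by 2.25 ± 0.22 (adjusted p = 0.00267). Of further known targets, egln3 was 6.49-fold higher (adjusted p = 0.0757) with a wide spread among the controls (SD 1.98), ddit4 was higher by 0.75 ± 0.61 (adjusted p = 0.453), sqor by 0.56 ± 0.30 (adjusted p = 0.262) and vegfaa by 0.21 ± 0.24 (adjusted p = 0.604), and none of the 4 passed with all arrays. The log2 difference of egln3 was 1.79 without control replicate 1, 3.76 without control replicate 2 (adjusted p = 0.00609) and 1.37 with the scan day as a block. That of sqor was 0.92 without control replicate 2 (adjusted p = 0.0374). In control replicates 1, 2 and 3 the mean of the HIF targets stood at -0.38, 0.40 and -0.02 from the mean of the controls, and that of glycolysis at -0.59, 0.66 and -0.10. igfbp1a and the 4 genes were chosen from knowledge of the study or of HIF, so they are not independent evidence.

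Several lists of tissue markers also shifted, and a difference in embryo stage between the groups was not tested as a cause. In somites and muscle 1 of 40 members fell and none rose, over all genes and adjusted over the list alone, and the median change was -0.39 (camera, adjusted p = 0.00694; 0.208 with an estimated correlation). The mean change of this list was -0.52, and -0.28 without control replicate 3. It stood at -0.34, -0.14 and 0.48 on control replicates 1, 2 and 3 and at -0.84, -0.50 and -0.22 on the Hif-1α arrays. With the experiment number as a block, 15 of its members fell and 1 rose. In the neural list 4 of 48 members fell and none rose, and 2 fell adjusted over the list alone. The median was -0.19 (adjusted p = 0.0260; 0.183 with an estimated correlation), and the eye field gene rx2 fell by 0.98 ± 0.16 (adjusted p = 0.0135). The neural list did not pass without control replicate 2 or Hif-1α replicate 2 (adjusted p = 0.0724 to 0.0734), nor after quantile normalization (adjusted p = 0.148) or in the deposited matrix (adjusted p = 0.147). In epidermis and hatching gland 4 of 31 members rose, and 7 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.00551; 0.264 with an estimated correlation). The cathepsin ctsl.1 rose by 3.96 ± 0.44 (adjusted p = 0.00386), and the list did not pass without Hif-1α replicate 3 (adjusted p = 0.0508). In yolk layer and endoderm 7 of 28 members rose, and 10 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.00304; 0.264 with an estimated correlation). The mean of this list stood at -0.17, 0.40 and -0.23 on control replicates 1, 2 and 3 and at 0.47, 0.56 and 0.56 on the Hif-1α arrays. The yolk layer regulator mxtx1 rose by 2.09 ± 0.34 (adjusted p = 0.0135) and the cathepsin ctsla by 1.00 ± 0.16 (adjusted p = 0.0127). The lists for notochord (adjusted p = 0.143; 2 of 18 members rose, and 3 adjusted over the list alone), blood and vessel (adjusted p = 0.872; 1 of 27 rose, and 0 adjusted over the list alone) and neural crest (adjusted p = 0.903; 0 of 21 changed with limma, and 0 adjusted over the list alone) did not pass. Neural crest had a median of 0.00 and a mean of -0.04. Blocked by experiment number, 8 neural genes fell, 9 epidermis genes rose, and 10 yolk layer genes rose and 2 fell. There 3 notochord genes rose and 1 fell, 2 blood and vessel genes rose and 4 fell, and 3 neural crest genes fell.

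Among the lists for stress and cell state, the interferon response had 7 of 18 members that rose, and 8 rose and 1 fell adjusted over the list alone. Its median was 0.53 (camera, adjusted p = 0.000596; 0.183 with an estimated correlation), and the transcription factor irf1b rose by 2.51 ± 0.35 (adjusted p = 0.00766). Of 36 oocyte and germline transcripts 15 rose and 1 fell, and 21 rose and 1 fell adjusted over the list alone. Their median was 0.62 (adjusted p = 2.28e-06; 0.208 with an estimated correlation), with tdrd9, a helicase of the germline, higher by 2.08 ± 0.21 (adjusted p = 0.0032) and org by 2.06 ± 0.26 (adjusted p = 0.00584). In the cell cycle list 7 of 42 members fell and 1 rose, and 12 fell and 2 rose adjusted over the list alone, with a median of -0.30 (adjusted p = 2.93e-06; 0.208 with an estimated correlation). The ribonucleotide reductase rrm1 fell by 1.15 ± 0.16 (adjusted p = 0.0117), whereas ccna1, a cyclin of germ cells, rose by 1.46 ± 0.21 (adjusted p = 0.00992). In the circadian clock 5 of 30 members rose and 2 fell, and 7 rose and 2 fell adjusted over the list alone. The median was 0.28 (adjusted p = 0.0200; 0.183 with an estimated correlation), and aanat2, an enzyme of melatonin synthesis, fell by 1.55 ± 0.18 (adjusted p = 0.00437). In heat shock 2 of 19 members fell, and 6 adjusted over the list alone, with a median of -0.31 (adjusted p = 0.0200; 0.264 with an estimated correlation). Its mean stood at 0.17, -0.27 and 0.09 on control replicates 1, 2 and 3 and at -0.46, -0.18 and -0.32 on the Hif-1α arrays, so control replicate 2 lay within their range. This list did not pass without control replicate 1 or Hif-1α replicate 1 (adjusted p = 0.0566 to 0.0685). The p53 and DNA damage list had 4 of 29 members that rose, and 6 adjusted over the list alone, with a median of 0.11 (adjusted p = 0.0418; 0.183 with an estimated correlation). It did not pass with the experiment number as a block (adjusted p = 0.0589) or with only the compared groups in the fit (adjusted p = 0.0538), nor without control replicate 2, Hif-1α replicate 1, Hif-1α replicate 3 or any 1 of the Hif-3α replicates (adjusted p = 0.0508 to 0.0733). The unfolded protein and amino acid response did not pass (adjusted p = 0.961). Of its 37 members 3 rose and 4 fell, and 4 rose and 6 fell adjusted over the list alone. The transcription factor cebpb rose by 1.42 ± 0.16, and asns and phgdh, enzymes of asparagine and serine synthesis, fell by 1.13 ± 0.15 and 1.21 ± 0.16. Ribosomal proteins did not pass (adjusted p = 0.428), with 1 of 79 members lower and 0 adjusted over the list alone. By camera they passed upward with normexp and the 75th percentile (adjusted p = 1.89e-10). They passed downward with normexp and quantile normalization (adjusted p = 0.00514) and in the deposited matrix (adjusted p = 0.0374). Blocked by experiment number, 2 cell cycle genes rose and 13 fell, 9 circadian genes rose and 2 fell, 5 heat shock genes fell and 8 p53 genes rose. There 6 genes of the unfolded protein response rose and 6 fell, and 2 ribosomal genes rose and 2 fell.

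**Figure D3:**
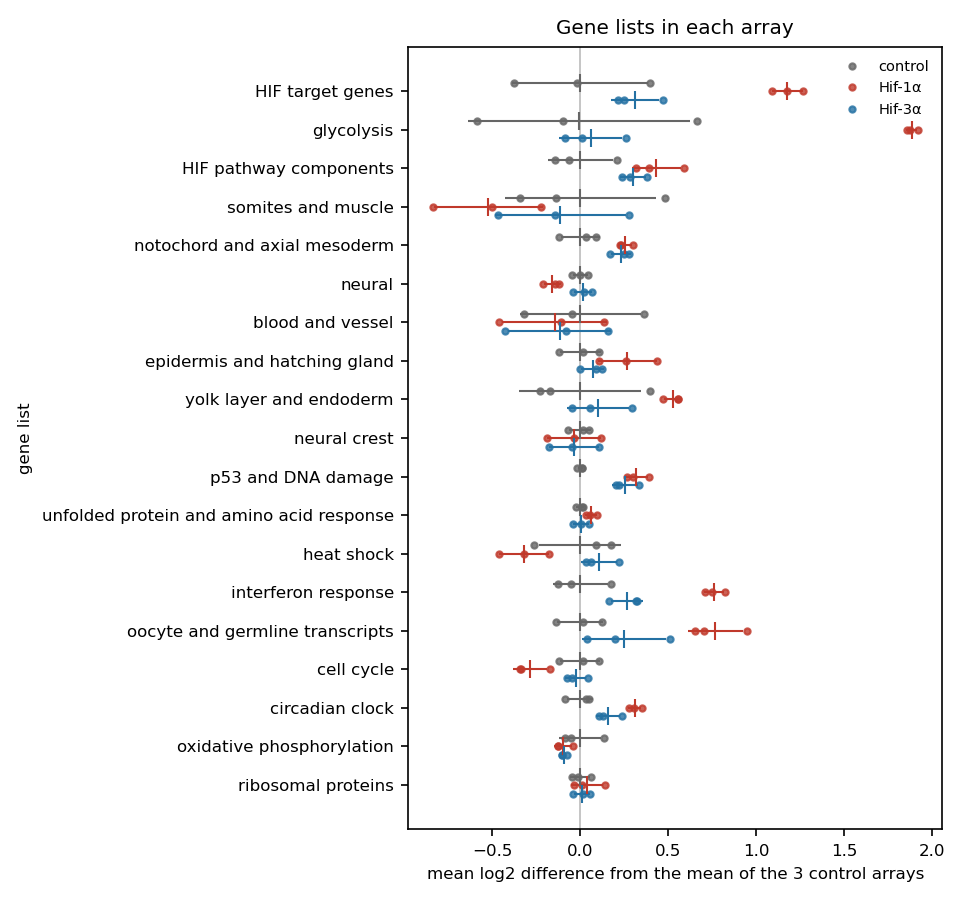
The horizontal axis gives the mean log2 difference of the members of each gene list from the mean of the 3 control arrays, for control, Hif-1α and Hif-3α arrays (points are arrays, ticks are means and bars are SD, n = 3). HIF target genes stood at 1.27, 1.09 and 1.17 on the Hif-1α arrays and at 0.25, 0.22 and 0.47 on the Hif-3α arrays, while control replicate 2 stood at 0.40.

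The number of changed genes differed with the arrays used. It was 527 without control replicate 1, 373 without control replicate 3, 395, 982 and 502 without Hif-1α replicates 1, 2 and 3, and 1212 and 1093 without Hif-3α replicates 2 and 3, and it was 4404 (2281 higher and 2123 lower) with the experiment number as a block. Centred on the median of each array 879 genes were higher and 1363 lower. With normexp background correction and the 75th percentile 5 genes passed, gapdhs among them, and 7 of the 13 lists, HIF targets and glycolysis among them. Scan day 3 held arrays of all groups, namely 2 control, 1 Hif-1α and 2 Hif-3α arrays. Within that day limma called 0 genes for Hif-1α against control (2260 at an unadjusted p under 0.05), and 4 with the scan day as a block (2242 unadjusted). These fits leave 2 and 3 residual degrees of freedom, and with the block the median SE rose from 0.19 to 0.27, so fewer calls there do not show smaller differences. Within the day gapdhs was higher by 4.73, pkma by 3.67, igfbp1a by 3.09, ndufa4b by 5.11, cox6b1 by 4.91 and eno1a by 4.46. The means of the lists within the day were 0.90 for HIF targets, 1.64 for glycolysis, -0.67 for somites, -0.21 for neural genes, 0.47 for the yolk layer, 0.76 for interferon, 0.71 for oocyte transcripts, -0.29 for the cell cycle, -0.08 for oxidative phosphorylation, 0.20 for epidermis, 0.27 for p53 and 0.23 for the circadian clock. Heat shock stood at -0.09 within the day, against -0.32 over all arrays. With the scan day as a block the lists for epidermis (adjusted p = 0.0576), p53 (adjusted p = 0.0726), heat shock (adjusted p = 0.664) and the circadian clock (adjusted p = 0.159) did not pass.

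Hif-3α embryos were compared with the same controls to ask which genes respond to Hif-3α. A single gene passed: casp6b.2, a caspase gene that no control array detected well above background, was at least 14.2-fold higher with Hif-3α (higher in 3 of 3 arrays, adjusted p = 0.0230). With limma 1191 genes had an unadjusted p under 0.05, where 977 would be found by chance, and 2465 did with the experiment number as a block, where 1 passed. Of the next genes by p, which did not pass, the related gene casp6b.1 (detected on 2 of 3 control arrays) was higher by 1.42 ± 0.15, the serine protease htra1a by 1.59 ± 0.18, the egg coat gene zp3d.2 by 3.28 ± 0.37 and myhz2 by at least 4.68-fold, each with an adjusted p of 0.0542. mixl1, a regulator of endoderm, was higher by 1.84 ± 0.25 (adjusted p = 0.135), sqor, which oxidises sulfide in mitochondria, by 2.13 ± 0.30 (adjusted p = 0.143), casp8 by 1.02 ± 0.15 (adjusted p = 0.165), gyg1a, which starts glycogen synthesis, by 1.45 ± 0.22 and vldlr by 1.67 ± 0.26 (both with an adjusted p of 0.171). Of other known HIF targets, none of which passed, the differences were 1.65 for ero1a, 1.01 for bnip3lb, 1.03 for hmox1a, 2.37 for egln3, 1.36 for ddit4, 0.17 for vegfaa and -0.18 for igfbp1a. That of egln3 was 1.47 without control replicate 1, 3.43 without control replicate 2 and 1.26 with the scan day as a block. The casp6b.2 call was lost without control replicate 1, control replicate 3, Hif-1α replicate 2 or Hif-3α replicate 3 (adjusted p = 0.0772 to 0.199) and with the scan day as a block, where limma called 0 genes (668 at an unadjusted p under 0.05). The count was 14 without control replicate 2, with mixl1, zp3d.2 and sqor among them, and 8 without Hif-3α replicate 2, with myhz2 among them.

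Of the 19 gene lists 3 passed for Hif-3α, although 0 members of the lists passed over all genes with limma, with or without the experiment number as a block. Oxidative phosphorylation was lower, with 68 of 79 members lower and a median of -0.15 (camera, adjusted p = 2.75e-07; 0.457 with an estimated correlation), and fry gave 0.274. Its mean was -0.10, and -0.03 without control replicate 3. The p53 and DNA damage list was higher, with 21 of 29 members higher, 2 of them past the threshold adjusted over the list alone, and a median of 0.10 (adjusted p = 0.0117; 0.202 with an estimated correlation). The notochord list was higher, with 16 of 18 members higher, 0 adjusted over the list alone and a median of 0.19 (adjusted p = 0.0479; 0.267 with an estimated correlation). The p53 list did not pass without Hif-3α replicate 2 or 3 (adjusted p = 0.0775 to 0.0866), and the notochord list did not pass without control replicate 3, Hif-1α replicate 2 or 3, or Hif-3α replicate 2 or 3 (adjusted p = 0.0589 to 0.259), nor with fry (0.0639), the mean of probes (0.0768) or only the compared groups in the fit (0.0571). Within scan day 3 the list means were -0.13, 0.27 and 0.23 for oxidative phosphorylation, p53 and notochord. HIF targets stood at 0.15 within the day (0.31 over all arrays) and glycolysis at -0.15 (0.06 over all arrays). Without control replicate 2, 10 lists passed, 5 without control replicate 1 or Hif-3α replicate 1, and 1 without Hif-3α replicate 3. HIF target genes did not pass with all arrays (median 0.12, adjusted p = 0.0685, with 1 member higher adjusted over the list alone), and neither did glycolysis (median 0.03, adjusted p = 0.979, with camera's direction downward). Both were among the 10 lists that passed without control replicate 2, the control in which they were highest, with means of 0.51 for HIF targets and 0.41 for glycolysis (adjusted p = 0.000117 and 0.00449; 0.219 each with an estimated correlation). HIF targets passed in 8 of 25 alternatives, also without Hif-3α replicate 1 (adjusted p = 0.00835), and glycolysis in 1. HIF pathway components, yolk layer, interferon and cell cycle (downward) also passed without control replicate 2 (adjusted p = 0.00739 to 0.0213), blood and vessel (downward) without control replicate 1 (adjusted p = 0.0230) and the circadian clock without Hif-3α replicate 1 (adjusted p = 0.0209). Oocyte transcripts did not pass (adjusted p = 0.0554; 0.769 with an estimated correlation) but did with the experiment number as a block (adjusted p = 0.0181) and without control replicate 1 or 2, Hif-1α replicate 1 or Hif-3α replicate 2 (adjusted p = 0.00631 to 0.0403). They also passed with quantile normalization, the median, the deposited matrix and no filter on dim probes. The same held with the filter on all arrays, only the compared groups, the mean of probes and the slide as a block (camera, adjusted p = 0.00718 to 0.0464 over these alternatives). Heat shock passed upward with the scan day as a block (adjusted p = 0.0334). The other lists had adjusted p-values of 0.0741 for HIF pathway components, 0.0741 for the circadian clock, 0.197 for interferon, 0.20 for blood and vessel, 0.222 for the cell cycle, 0.240 for the yolk layer, 0.241 for epidermis, 0.389 for the unfolded protein response, 0.448 for neural crest, 0.462 for heat shock, 0.610 for somites, 0.967 for neural genes and 0.979 for ribosomal proteins. Adjusted over the list alone, 2 circadian genes were higher, 2 interferon genes were higher and 1 lower, and 0 members of the lists not given here with such a count passed. Median and test had opposite signs for neural genes (median 0.03) and ribosomal proteins (median 0.02), both with camera's direction downward, and the unfolded protein response had a median of -0.02 and a mean of 0.00.

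The arrays of Hif-3α and Hif-1α embryos were compared directly, which tests for each gene whether the responses differed. gapdhs differed by -4.92 ± 0.29 log2 units (adjusted p = 0.000436), eno1b by -5.08 ± 0.50 (adjusted p = 0.00428), pkma by -3.66 ± 0.24 (adjusted p = 0.00223) and the glucose transporter slc2a3a by -3.04 ± 0.37 (adjusted p = 0.00983; 0.0556 without Hif-1α replicate 1). The photoreceptor transcription factor crx (well above background on 2 of 3 Hif-3α arrays) differed by -4.61 ± 0.27 (adjusted p = 0.000436) and cox5b2 by -2.30 ± 0.22 (adjusted p = 0.00418). The peptidase nln (adjusted p = 0.00422) and vamp1b (adjusted p = 0.00464), each well above background on 1 of 3 Hif-3α arrays, were also lower. The sodium channel scn1lab and the transporter slc22a13b were at least 6.48-fold and 5.35-fold lower. igfbp1a differed by -4.17 ± 0.56 (adjusted p = 0.0158), a call lost without Hif-1α replicate 1 or 3 or Hif-3α replicate 1 or 2 (adjusted p = 0.0550 to 0.0766). Of the genes that were higher with Hif-3α, adra1bb, well above background on 1 of 3 Hif-1α arrays, passed (adjusted p = 0.0119; 0.0568 to 0.0670 without Hif-3α replicate 2 or 3), and zp3d.2 differed by 2.04 ± 0.37 (adjusted p = 0.0488), a call lost without any 1 array other than control replicate 2 (adjusted p = 0.0540 to 0.157). sqor was higher by 1.57 ± 0.30 (adjusted p = 0.0572), and passed with the experiment number as a block (adjusted p = 0.0369) and without control replicate 1 or 2 (adjusted p = 0.0476 and 0.0133). It also passed with the median, normexp and quantile normalization, an intensity trend, array weights or only the compared groups (limma, adjusted p = 0.0214 to 0.0495). In all, 181 genes or transcripts differed, 37 higher and 144 lower with Hif-3α, and 171 of them also changed with Hif-1α against control. Both comparisons hold the Hif-1α arrays, so this overlap is not independent evidence.

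Among the lists, 7 of 23 glycolytic genes and 5 of 39 HIF targets were lower with Hif-3α than with Hif-1α, and none was higher. Adjusted over the list alone, 11 glycolytic genes were lower, and 13 HIF targets were lower and 1 higher. The list medians were -0.46 (camera, adjusted p = 9.14e-09) and -0.50 (adjusted p = 3.82e-08), each with an adjusted p of 0.209 with an estimated correlation. The oocyte list (1 of 36 members lower over all genes, 6 lower and 1 higher adjusted over the list alone, median -0.41, adjusted p = 2.27e-07), the interferon list (1 of 18 lower, 2 adjusted over the list alone, median -0.36, adjusted p = 0.000400), the yolk layer list (0 of 28 with limma, 2 lower adjusted over the list alone, median -0.31, adjusted p = 0.00112) and the epidermis list (1 of 31 lower, 3 adjusted over the list alone, median -0.13, adjusted p = 0.00623) were lower. Their adjusted p-values with an estimated correlation were 0.239, 0.186, 0.346 and 0.365. The cell cycle (10 of 42 higher and 1 lower adjusted over the list alone, median 0.26, adjusted p = 2.34e-06), heat shock (1 of 19 higher adjusted over the list alone, median 0.44, adjusted p = 0.000400), somites (0 of 40 adjusted over the list alone, median 0.31, adjusted p = 0.00311) and neural genes (1 of 48 higher adjusted over the list alone, median 0.18, adjusted p = 0.00623) were higher, although 0 of their members passed over all genes without the block. With an estimated correlation their adjusted p-values were 0.273, 0.239, 0.239 and 0.186. Oxidative phosphorylation was higher by camera (adjusted p = 0.000400; 0.392 with an estimated correlation) and by its median of 0.20, but its mean was 0.00, the 2 members that passed over all genes were lower, and 8 members were higher and 4 lower adjusted over the list alone. This mean was -0.05 after quantile normalization and -0.02 to 0.03 with 1 array left out. The mean of somites was 0.41, against 0.25 without Hif-1α replicate 1 and 0.21 without Hif-3α replicate 3. The lists for HIF pathway components (adjusted p = 0.311), notochord (0.818), blood and vessel (0.555), neural crest (0.772), p53 (0.690), the unfolded protein response (0.513), the circadian clock (0.237) and ribosomal proteins (0.378) did not pass. Among their members vhl was lower by both counts (lost over all genes without control replicate 1 or any 1 Hif-1α or Hif-3α array, adjusted p = 0.0634 to 0.155). In the unfolded protein response asns was higher and cebpb lower over all genes (both lost without any 1 array other than control replicate 2, adjusted p = 0.0550 to 0.163), and 2 members were higher and 1 lower adjusted over the list alone. Of the circadian genes aanat2 was higher over all genes (lost without control replicate 1, Hif-1α replicate 1 or 2, or any 1 Hif-3α array, adjusted p = 0.0546 to 0.121), and 1 was higher and 3 were lower adjusted over the list alone. The other 5 of these lists had 0 members past the threshold by either count without the block. With the experiment number as a block 10 glycolytic genes, 9 HIF targets, 9 oocyte transcripts and 2 genes each of the interferon, yolk layer and epidermis lists were lower. There 5 somite genes, 2 neural genes and 1 heat shock gene were higher, as were 1 cell cycle gene (1 lower), 1 of oxidative phosphorylation (3 lower), 2 of the unfolded protein response (1 lower) and 1 of notochord, and 1 of blood and vessel was lower. Median and mean had opposite signs for notochord (0.04 and -0.02) and for blood and vessel (0.00 and 0.03).

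The direct comparison also moved with the arrays used. The count was 57, 96 and 79 without Hif-1α replicates 1, 2 and 3, 95, 56 and 68 without Hif-3α replicates 1, 2 and 3, 280 without control replicate 2, 889 (371 higher and 518 lower) with the experiment number as a block, and 6 with normexp background correction and the 75th percentile, gapdhs and pkma among them, where 6 of the 11 lists passed. Within scan day 3 limma called 0 genes (1264 at an unadjusted p under 0.05), and 3 with the scan day as a block (1148 unadjusted). Within that day gapdhs differed by -5.05, pkma by -3.78, crx by -4.71 and slc2a3a by -2.71, and between the Hif-1α and Hif-3α arrays that shared a slide by -4.95, -4.02, -4.85 and -2.70. The values within the day and on the shared slide rest on the same single Hif-1α array, replicate 2, so they are not separate checks. The list means within the day were -1.78 for glycolysis and -0.75 for HIF targets, against -1.91 and -0.87 on the shared slide. The epidermis list did not pass without Hif-1α replicate 3 (adjusted p = 0.129, mean -0.11 against -0.20) or with the scan day as a block (adjusted p = 0.0772). Oxidative phosphorylation did not pass with the scan day as a block (adjusted p = 0.655), and the neural list did not pass after quantile normalization (adjusted p = 0.0609). Ribosomal proteins passed by camera downward with normexp and the 75th percentile (adjusted p = 6.95e-12) and upward with normexp and quantile normalization (adjusted p = 0.0159).

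The responses to Hif-1α and Hif-3α were set against each other across the 19541 genes, which are not independent replicates. The log2 changes against control had a Pearson correlation of 0.573, where simulated groups with no change against the same controls gave 0.499 (0.475 to 0.525). These simulations take all arrays as independent. With same-numbered arrays correlated as measured, unchanged groups gave 0.631 (0.606 to 0.657). The correlation of 0.573 lies below that range, but unchanged groups hold none of the Hif-1α changes, which widen the spread of that response. The correlation can therefore neither show nor exclude a shared response. The covariance was 0.120, above the independent simulations (0.0411, 0.0384 to 0.0444) and the correlated ones (0.0353, 0.0331 to 0.0378). The independent simulations gave all groups the same spread, while some genes varied widely among the controls. Whether the higher covariance comes from a shared response was not tested. 1 gene, casp6b.2, passed in both comparisons. The independent simulations, which share the controls but hold no effects, gave 0.01, and the correlated ones gave 0. Independent lists, which leave out the shared controls, gave 0.0574. Part of the excess over the independent lists may come from the shared controls, since 3 control arrays cannot be divided into separate sets of 2. The 1 gene is not read as a shared effect. The correlation ranged from 0.468 without Hif-3α replicate 1 to 0.689 without control replicate 2. The count of genes passing in both was 14 without control replicate 2, 7 without Hif-3α replicate 2, and 0 without control replicate 1 or 3, Hif-1α replicate 2 or Hif-3α replicate 3.

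**Figure D4:**
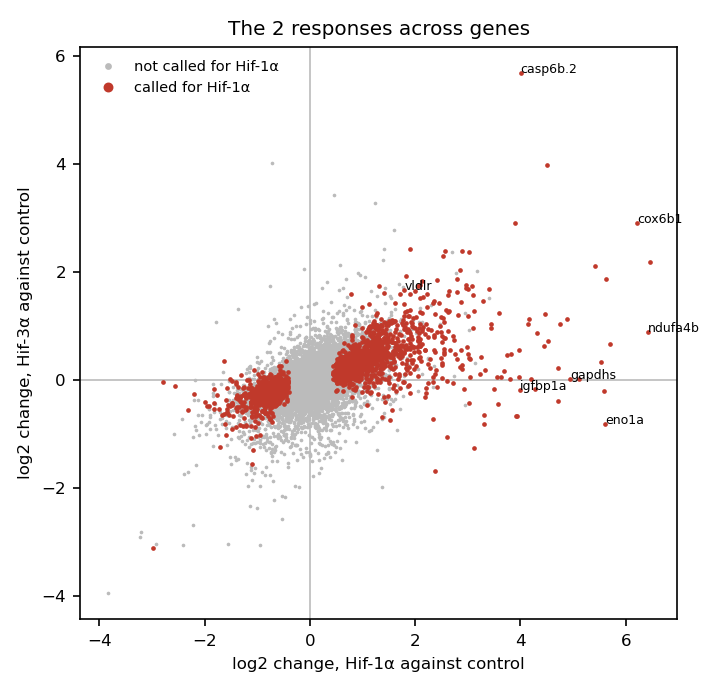
Each point is a gene (red if it changed with Hif-1α), with its log2 change for Hif-1α against control on the horizontal axis and for Hif-3α against control on the vertical axis (differences of means, n = 3 arrays a group). The Pearson correlation across genes was 0.573, against 0.499 in simulated groups without change and 0.631 where same-numbered arrays were correlated as measured.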

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

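Alternatives with the scan day as a block and with an experiment number left out were chosen after the data had been seen, and all others before. The number of arrays limits the precision. Normexp with the 75th percentile raised the median standard error for Hif-1α against control from 0.19 to 0.34 and shifted the median of all genes by -0.20, and 1 of the 62 named genes that had passed still did. With normexp and quantile normalization the error was 0.12, the shift -0.02 and the number 60. Centring on the median shifted it by -0.12 (879 higher and 1363 lower). Over the alternatives, the named genes that had passed gave 2133 values, of which 1590 still passed, 543 no longer did and 0 changed sign in limma. A fold given as "at least" holds for the main processing alone. Over the alternatives the log2 difference went down to 0.44 for adra2db and 0.47 for myhz2 with Hif-1α. That of casp6b.2 with Hif-3α went down to 1.24. Lists that had passed gave 675 values, of which 598 still passed, 75 did not and 2 had the opposite direction. Named genes that had not passed gave 550 values, of which 18 passed and 8 changed sign, and lists that had not passed gave 750, of which 51 passed. With the experiment number as a block 1857 of the 1858 genes changed with Hif-1α still passed, and of named genes and lists only the p53 list lost its call. Of the genes changed with Hif-1α, 1585 were also among the 1722 found after quantile normalization and 1544 among the 1669 found in the deposited matrix. The cause of the differences was not tested except where fewer arrays or groups show it.

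For Hif-1α against control the 1858 genes became 5 with normexp and the 75th percentile (5 higher and 0 lower: gapdhs, slc2a3a, dgat1b, hvcn1 and a transcript without a symbol, named after their values were seen). They became 705 without the filter on dim probes, 696 with only the compared groups, 4404 with the experiment number as a block, 776 at an adjusted p with at least 2-fold, 1209 at an unadjusted p with at least 2-fold, and 4 with the scan day as a block, all transcripts without a symbol. With the experiment number as a block they were 533, 3781 and 2 without number 1, 2 and 3. With 1 array left out they ranged from 373 (control replicate 3) to 2062 (control replicate 2).

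For Hif-3α against control the 1 gene became 0 with normexp and either scaling, without the filter, with the filter on all 9 arrays, with only the compared groups, with the scan day as a block, and with the experiment number as a block without any 1 number. It became 2 in the deposited matrix (casp6b.2 and a transcript without a symbol), 6 with the mean of probes, 10 with every probe on its own and 225 at an unadjusted p with at least 2-fold. Among the 6 was hif1al, the gene of the injected RNA (5.18, adjusted p = 1.42e-06), beside casp6b.2, casp6b.1, myhz2, zp3d.2 and vldlr. The count of 10 is one of probes, and the hif1al probes that rose each passed over all probes. With 1 array left out the count ranged from 0 to 14. With limma the count at an unadjusted p under 0.05 was 1191.

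For Hif-3α against Hif-1α the 181 genes became 6 with normexp and the 75th percentile (the 5 given for Hif-1α and pkma), 420 with normexp and quantile normalization, 81 without the filter, 391 with an intensity trend, 361 with array weights, 300 with every probe on its own, 889 with the experiment number as a block, 568 at an unadjusted p with at least 2-fold and 3 with the scan day as a block (all without a symbol). With the experiment number as a block they were 38, 38 and 2 without number 1, 2 and 3. With 1 array left out they ranged from 56 to 280.

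The 1 gene that passed in both comparisons became 0 with normexp and either scaling, without the filter, with the filter on all 9 arrays, with only the compared groups and with the scan day as a block, 2 in the deposited matrix, 4 with the mean of probes, 6 with every probe on its own, and 136 at an unadjusted p with at least 2-fold, and ranged from 0 to 14 with 1 array left out. The correlation of the responses was 0.364 with normexp and the 75th percentile, and 0.468 to 0.689 with 1 array left out.

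With an estimated correlation 0 lists passed in any comparison (limma's camera), where fry passed 15, 1 and 8. The 3 lists for Hif-3α against control became 5 with the median, with normexp and the 75th percentile, in the deposited matrix, with the filter on all 9 arrays, with the mean of probes and with the slide as a block, 6 without the filter, and 1 with fry. They ranged from 1 to 10 with 1 array left out, those for Hif-1α from 11 to 13 and those for the direct comparison from 10 to 11.

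Values changed sign for these known targets, injected genes and lists that had passed. The gene value of hif1al for Hif-3α was 5.18 with the mean of its probes, 0.0338 without control replicate 2 and 0.02 without Hif-3α replicate 1, since its brightest probe did not move, and with 1 array left out it and that probe ranged from -0.0734 to 0.0338. Probe A_15_P731526 ranged from 6.27 to 6.58, A_15_P404495 from 5.71 to 6.03 and A_15_P281686 from 8.41 to 8.62. vegfaa was -0.10 for Hif-1α with normexp and the 75th percentile. In the direct comparison it was 0.0245 with the median, 0.34 and 0.0366 with normexp and either scaling, 0.00044 in the deposited matrix and 0.0201 without Hif-3α replicate 2. igfbp1a for Hif-3α was 0.36 without control replicate 2 and 0.07 without Hif-3α replicate 2, and ranged from -0.70 to 0.36. With normexp and the 75th percentile the mean of the circadian clock for Hif-1α was -0.0283 (0.31 before; adjusted p = 0.127) and that of interferon in the direct comparison 0.0161 (-0.49 before; adjusted p = 0.140). There the neural list turned downward by camera with a mean of 0.0717 (adjusted p = 0.977), as did oxidative phosphorylation with a mean of -0.0761 (adjusted p = 0.159). The mean of oxidative phosphorylation in the direct comparison, 0.00153 with all arrays, was below 0 in 11 of 25 alternatives, the lowest being that -0.0761. The other 10 were quantile normalization, normexp with quantile normalization, the deposited matrix, the mean of probes, the slide or the scan day as a block, and without Hif-1α replicate 1 or 3 or Hif-3α replicate 2 or 3.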

Other observations

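The tests of lower signal, of slide and scan day for same-numbered arrays, of scan day against each control of the day, and of carried-over RNA were chosen after the results had been seen, as were the gene families, the account without control replicate 2, the control lists and the unnamed probe. Control replicate 2 was looked at apart after its HIF target genes and glycolysis had been seen to be high, so higher Hif-3α values without it follow in part from that choice and are no evidence of a response. Without it limma called 14 genes or transcripts for Hif-3α against control. Among them were mixl1 (2.17), zp3d.2 (3.73), sqor (2.49, adjusted p = 0.0150), sesn3 (1.53) and mief2 (1.08), all higher by the log2 value given.

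Genes were also grouped by the letters before the number in their symbols, which gave 126 families of at least 10 members. Of the atp family, the ATP synthase and ATPase genes, 11 of 58 members fell with Hif-1α, or 19.0%, against 4.75% of all genes in the test (one-sided Fisher's exact test, adjusted p = 0.00934). The members that fell included atp5mc1, atp5f1c, atp5pb and atp5f1b, which overlap the oxidative phosphorylation list. Fisher's test takes genes as independent, whereas the estimated correlation between genes of that list was 0.21. The family's p-value is therefore no independent support, and the counts are a description. No other family passed in Hif-1α against control or in the direct comparison, and the mitochondrial ribosomal mrpl family had 7 of 39 members lower (adjusted p = 0.135). A probe whose transcript has no symbol, A_15_P192266, stood at 3.78, 0.62 and 2.91 on Hif-1α replicates 1, 2 and 3, at -3.84, -3.65 and -3.74 on the controls and at -3.42, -3.43 and -3.77 on the Hif-3α arrays. It was picked as the probe without a symbol that rose most on the Hif-1α arrays above all others, so its height there follows from that choice. Whether it measures the injected Hif-1α RNA is open, since no table names its transcript.

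The 3 against 3 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 1858 genes for Hif-1α against control, and the highest other split gave 0. For Hif-3α against control these numbers were 1 and 0, and for Hif-3α against Hif-1α 181 and 1. In each comparison 1 of the 10 splits, the real one, gave as many genes. Compared with the other splits that part all same-numbered arrays, 4 splits with the real one, the highest other count was 0 in each comparison.

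The gene changes with Hif-1α were weighed against the lower signal of the Hif-1α arrays and against slide and scan day. After quantile normalization, which gives all arrays 1 distribution, 85.3% of the changed genes still passed. The main values were already scaled to each array's 75th percentile, and quantile normalization left the median standard error at 0.192 (0.193 before). Most calls would therefore stay whether or not lower signal had a part, so this test cannot decide on it. With normexp and the 75th percentile, which treats the background in another way, 5 genes passed. Of 1533 genes that differed by over 1 log2 unit on the other days, 77.9% had the same direction within scan day 3, on other slides (79.2% and 76.8% against each control of the day alone, 75% set in advance as the bound), where 45.5% of all genes were higher, which argues against slide and scan day as the whole cause. With the scan day as a block gapdhs was higher by 4.73 ± 0.38 (4.95 ± 0.29 without it) and no longer passed (adjusted p = 0.0549), since 3 residual degrees of freedom remain and the median standard error rose from 0.19 to 0.27. No other day held more than 1 group, so the value with the block is the difference within scan day 3 and no separate check. Scan day 3 held 1 Hif-1α array, so a part of slide or scan day in the size of single genes' changes stays open, and a biological effect of Hif-1α stays open too.

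Arrays with the same number deviated together in all 3 groups. Hif-1α replicates 1 and 3 shared a slide and a scan day, yet their difference had a correlation across genes of 0.434 with the same difference in control and 0.532 in Hif-3α, which argues against slide and scan day as the whole cause. Over the brightest of 3 equal classes of genes the number 1 arrays had correlations of 0.422, 0.559 and 0.751 in the 3 comparisons. Over the other genes these were 0.265, 0.334 and 0.517. The lowest same-number correlation in the brightest class, of number 2, was 0.134. These values argue against fewer probes above background on the number 1 arrays as the whole cause. In all 3 groups, number 1 minus number 3 was negative for somites and muscle (-0.83 in control, -0.62 in Hif-1α and -0.74 in Hif-3α) and for blood and vessel (-0.68, -0.59 and -0.60) and positive for oocyte transcripts (0.26, 0.24 and 0.31), each outside the central 95% of random lists of the same size, as no other list was in all 3 groups. A candidate explanation is that the embryo stage differed between the microinjection experiments, which needs this opposite shift of somites and oocyte transcripts in each of the 3 groups. It remains a hypothesis, with other differences between the experiments untested. For Hif-1α against control the mean of somites was also lower (-0.52) and that of oocyte transcripts higher (0.77), while blood and vessel did not pass (mean -0.15). Whether the embryo stage differed between the groups was not tested.

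HIF target genes and glycolysis moved apart among the controls: control replicate 2 lay above the other controls by a median of 0.49 (29 of 39 members higher) and 0.64 (19 of 22), above each of 10000 random lists of like expression, and control replicate 1 lay at -0.44 (7 higher) and -0.75 (2 higher), below each of them. Other lists also lay outside all random lists. These were the yolk layer (0.53, 25 of 28 higher) and oxidative phosphorylation (-0.18) in control replicate 2. In control replicate 1 they were somites (-0.27), blood and vessel (-0.43) and the cell cycle (0.15). In control replicate 3 they were somites (0.28), oxidative phosphorylation (0.23), notochord (-0.24) and the yolk layer (-0.46). The random lists draw genes singly, so lists whose members vary together can fall outside them. Over 180 genes that differed between Hif-3α and Hif-1α, these differences of control replicates 1, 2 and 3 had correlations of -0.475, 0.487 and -0.151 with the difference between Hif-1α and Hif-3α arrays, and over all genes -0.05, 0.355 and -0.23. RNA carried over from a Hif-1α sample would raise all genes high in Hif-1α by a like share. At the share that the list members give, 8.95%, the 32 genes outside both lists that were at least 8-fold higher in Hif-1α than in Hif-3α lay a median of -0.94 log2 units from the needed level (quartiles -1.60 and -0.38), 29 of them below it. The 2 lists were looked at because they were high in control replicate 2, which can raise that share. Some of the 32 genes, such as adra2db (-8.38) and scn1lab (-7.63), lay below the lowest level well above background on that array (-6.30). The test therefore cannot decide on RNA carried into control replicate 2. No biological explanation was tested, since the labels give the control embryos no difference in treatment.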
